A study of Mus musculus with 87 samples.

How the data were processed

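The series holds polyadenylated RNA sequencing of 87 mouse samples: haploid embryonic stem cells of 3 Dnmt genotypes, semi-cloned embryos at 3 stages before implantation, and tissues at E18.5 and P1. The protocol describes both a kit that selects poly(A) RNA and a kit for very low input, and which libraries were made with which kit is not given in the sources used here. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.6, aligned to mm10 with HISAT2 2.1.0 and assigned to genes with featureCounts 1.6.4, and DESeq2 was used for differential expression. The handling of strand and of reads that map to several places is not stated, so overlapping or near-identical genes cannot be told apart.

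The deposited values are raw counts of reads per gene, per the labels, in 10 tables with the same 25277 gene symbols. Every value was checked to be a whole number, 0 symbols occurred more than once and no transposon entries were present, so transposon expression was not analysed here. Samples were joined to columns by name. For 11 columns of the embryo tables, named O48 with a stage and a number, no sample carries that name, and they were assigned to the pWT samples of the same stage and number by elimination. The meaning of O48 is not given in the sources used here, and all 3 embryo comparisons rest on that assignment.

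Library totals of assigned counts ranged from 6.1 to 37.4 M. Between libraries of one group the chi-square per degree of freedom was at least 3.65, so the spread between libraries exceeded counting noise in every group. Sex was read from 4 Y-linked genes, and haemoglobin content from the sum of 10 globin genes.

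Each comparison used the libraries of its own stage, tissue and batch, and the 3 genotypes of haploid cells shared one fit. Genes were kept with filterByExpr (minimum count 10) and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) after TMM scaling. P values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The standard error of a log2 fold change is the fold change divided by the square root of its F statistic. Printed CPM use library totals and are not TMM-scaled, so a ratio of CPM can differ from the fitted fold. In all, 17 comparisons were made, and 4 contrasts tested whether an effect differed between tissues, stages or genotypes. Gene positions, GC content and transcript length came from the GENCODE annotation of mm10, release M21, and covered 24373 of the genes (96.4%).

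The choice of comparisons, tests, most alternatives, gene lists and the rule for named genes was made before the data were examined. The 39 lists hold 568 entries, of which 559 were found. Each list with at least 3 tested members was tested in the comparisons its tissue concerns, with camera of limma 3.58.1 at its preset correlation of 0.01, and the 422 p values were adjusted together, giving 104 under 0.05. As camera's preset correlation is low, each list was also tested with the correlation estimated from the data, which left 0 under 0.05, and with fry, which gave 7 under 0.05, 5 of them among the 104. With 1 library left out, a list's new p took the place of its own among the 422 before adjustment. Counts "adjusted over the list alone" apply the Benjamini-Hochberg method to the members of that list.

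Genes could be named under 5 rules. They are the deleted genes; the measured genes of the paternally methylated imprinted clusters; up to 6 called genes with the largest rise and 6 with the largest fall per comparison, with a mean of at least 5 CPM in the higher group and no overlap between the groups, leaving out predicted genes, pseudogenes and sex check genes; the 4 members with the smallest p of each list that passed or held at least 3 called members; and other imprinted genes called in at least 2 tissues or stages. Examples in the text were taken where possible from genes whose call held without any 1 library. Sectm1a and Gm11694 fall outside these rules and were chosen after their values were seen, and so were the blastocyst values of Rmi2, Bag1 and Spp1.

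Alternatives chosen at that time were the Wald test of DESeq2 1.42.0, median-of-ratios scaling, no filter on low counts, the replicate number as a block, larger or smaller sets of libraries in the fit and each library left out. Alternatives added after the data were seen took out trends on GC content or transcript length in 25 bins per library, left out haemoglobin genes, chromosome 5 or chromosome X, or crossed the replicate numbers. The covariance of TKO and STOP fold changes was compared with 20 simulations of groups without an effect set against the same control libraries. The procedure was tested on simulated data with known changes: a 4-fold change was recovered for 86.4% of genes in the TKO comparison, 75.8% in STOP, 4.5% in 2C embryos, 39.4% in morulae and 66.7% in blastocysts. In pTKO brain, heart, kidney, liver and lung it was recovered for 93.9%, 69.7%, 54.5%, 0% and 62.1%, in pIR E18.5 heart and liver for 97% and 92.4%, and in P1 heart, kidney, liver and lung for 90.9%, 93.9%, 93.9% and 87.9%. Unchanged genes that were called numbered 2 for TKO, 9 for STOP, 1 in 2C embryos, 3 in morulae and 3 in blastocysts. In the pTKO tissues, in the same order, they numbered 20, 24, 12, 0 and 3. In the pIR tissues they numbered 10, 15, 17, 12, 14 and 19. In pTKO heart 3, 17 and 46 genes with a 1.5-, 2- and 4-fold change were recovered. False calls exceeded the share of all calls that the adjusted p threshold allows in most comparisons. They did so by most in pTKO heart and kidney, and also clearly in pTKO brain, P1 heart and P1 lung. Only TKO against WT, STOP against TKO, blastocysts and pTKO liver, where no gene was called, stayed within that share.

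Results that rest on genes withheld for evaluation were left out.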

Results

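Polyadenylated RNA was sequenced in 87 mouse libraries from androgenetic haploid embryonic stem cells, which carry only a genome of paternal origin, and from embryos and tissues of semi-cloned mice. In semi-cloning such a haploid cell is injected into an oocyte in place of a sperm. The haploid cells were labelled WT (n = 3), TKO (n = 3) and STOP (n = 2) for their Dnmt genotype. Embryos labelled pWT and pIR were sampled at the 2C stage (n = 4 each), as morulae (pWT n = 3, pIR n = 4) and as blastocysts (n = 4 each). Before birth, at E18.5, a first batch held brain, heart, kidney, liver and lung of pTKO and pWT (n = 2 each), and a second batch held heart and liver of pIR and pWT (n = 4 each). At postnatal day 1 (P1) heart, kidney, liver and lung of pIR (n = 2) and pWT (n = 3) were sampled. The meaning of pIR, of STOP and of the prefix p is not given in the sources used here.

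Total gene counts per library ran from 16.8 to 24.5 M (mega) in haploid cells. They ran from 6.1 to 7.5 M in pIR and from 10.9 to 24 M in pWT 2C embryos, from 7.7 to 17 M in morulae and from 9.7 to 14.9 M in blastocysts. E18.5 libraries held 10.7 to 37.4 M in batch 1 and 16.3 to 23.8 M in batch 2, and P1 libraries held 13.9 to 21 M. The summed count of 4 Y-linked genes was at most 4 in any library. Levels are CPM (counts per M of the library total) as mean ± SD over the libraries of a group, log2 fold changes carry ± SE and positions are mm10. Nothing states that libraries of one group came from separate cultures or animals, so each p measures the spread between these libraries. The plot of genes called per comparison gives the counts taken up below.

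**Figure D1:**
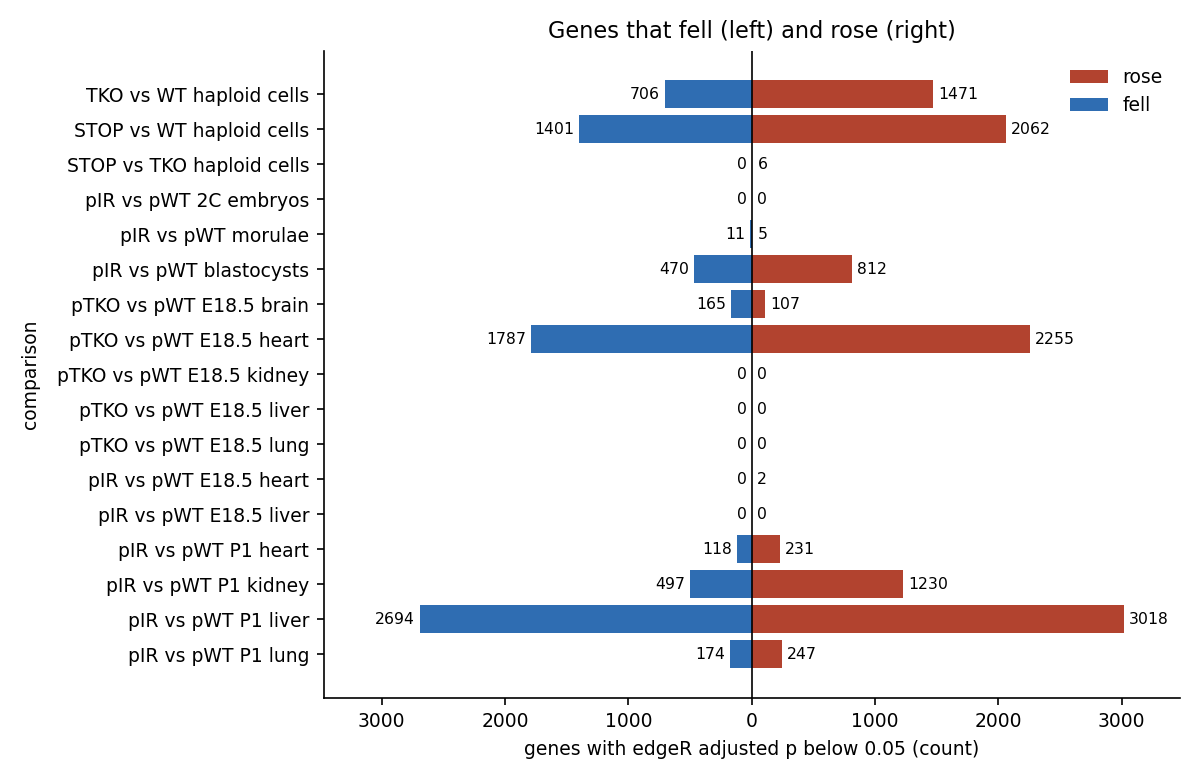
Number of genes that rose (right) and fell (left) in each comparison, with edgeR adjusted p under 0.05. P1 liver (3018 rose, 2694 fell) and pTKO E18.5 heart (2255 rose, 1787 fell) held the highest counts, and 2C embryos, pTKO kidney, liver and lung and pIR E18.5 liver held 0.

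The TKO cells were compared with WT to ask what haploid cells of that Dnmt genotype express, and the Dnmt genes themselves were read first. Dnmt1, the maintenance methyltransferase (chromosome 9, 20907209–20959888), stood at 71.1 ± 2.69 against 422 ± 3.36 CPM (log2 fold change -2.62 ± 0.071, edgeR adjusted p = 6.44e-07). Dnmt3a (chromosome 12, 3806007–3914443) and Dnmt3b (chromosome 2, 153649450–153687730), the de novo methyltransferases, stood at 11.3 ± 0.74 against 68.8 ± 5.49 CPM and at 24.1 ± 2.59 against 136 ± 12.0 CPM. Their log2 fold changes were -2.65 ± 0.11 and -2.54 ± 0.11 (both edgeR adjusted p = 6.93e-06), and every TKO library lay below every WT library for each gene. In STOP cells Dnmt1 stood at 587 ± 20.4 CPM, above WT (log2 fold change 0.38 ± 0.074, edgeR adjusted p = 0.0127), so the RNA level does not check that label. That call was lost without any 1 of the WT libraries 1, 2 and 3 (Dnmt1 adjusted p = 0.0583, 0.05 and 0.0579) or of STOP 1 and 2 (0.0655 and 0.119). Dnmt3a and Dnmt3b in STOP had log2 fold changes of -0.41 ± 0.11 and -0.22 ± 0.11 (edgeR adjusted p = 0.0336 and 0.17), and Dnmt3a did not pass without WT 1, 2 or 3 (0.0735, 0.103 and 0.103) or STOP 1 or 2 (0.124 and 0.211).

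Some germ cell genes and some imprinted genes were higher in TKO cells. Rhox5, an X-linked homeobox gene (chromosome X, 37804842–37808876), rose from 21.8 ± 5.05 to 333 ± 70.7 CPM (log2 fold change 3.90 ± 0.24, edgeR adjusted p = 0.000101). Dazl, an RNA-binding protein of germ cells (chromosome 17, 50279395–50293636), rose from 12.7 ± 1.84 to 148 ± 33.4 CPM (log2 fold change 3.51 ± 0.21, edgeR adjusted p = 9.94e-05). Of 30 measured germ cell genes whose promoters are methylated in somatic cells, 11 rose, 1 fell and 18 did not pass. Fkbp6, Tuba3a and the meiotic cohesin gene Smc1b were among those that rose (log2 fold changes 2.69 ± 0.21, 2.17 ± 0.26 and 1.66 ± 0.27). Adjusted over the list alone 12 rose and 1 fell (camera adjusted p = 0.000848, and adjusted p = 0.826 with an estimated correlation), and without TKO replicate 3 the list did not pass (adjusted p = 0.376). Of 15 maternally expressed genes of maternally methylated imprinted clusters 5 rose, in all and adjusted over the list alone (camera adjusted p = 0.127). Grb10, which encodes an adaptor that restrains growth signalling, was 1 of them (log2 fold change 1.87 ± 0.30, edgeR adjusted p = 0.0061), as was Igf2r, the receptor that clears Igf2 (log2 fold change 0.94 ± 0.14). Of 20 paternally expressed genes of maternally methylated clusters 2 rose and 4 fell, in all and adjusted over the list alone (median -0.06, camera adjusted p = 0.167). Of the paternally methylated clusters, the maternally expressed RNAs Meg3 and Rian rose in the fit of all 3 genotypes (log2 fold changes 1.84 ± 0.45 and 1.44 ± 0.39, edgeR adjusted p = 0.0303 and 0.0408). Their levels were low, 2.58 ± 1.38 and 4.07 ± 1.53 CPM. Meg3 did not pass without WT 1, 2 or 3 or TKO 2 (adjusted p = 0.117, 0.0801, 0.109 and 0.1) nor with TKO and WT alone in the fit (0.0544), and neither did Rian (0.149, 0.0645, 0.156, 0.139 and 0.0596). H19 and Igf2 had log2 fold changes of -1.01 ± 0.93 and -0.74 ± 0.56 (edgeR adjusted p = 0.481 and 0.384).

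Dppa3, which encodes a maternal factor that protects methylation in the zygote, rose to 47.6 ± 20.3 from 6.57 ± 1.2 CPM (log2 fold change 2.79 ± 0.27, edgeR adjusted p = 0.00108). Klf4, a pluripotency factor, fell to 224 ± 29.8 from 369 ± 20.8 CPM (log2 fold change -0.76 ± 0.13, edgeR adjusted p = 0.00654). Of 15 naive pluripotency genes 2 fell and 1 rose, also adjusted over the list alone (median -0.33, camera adjusted p = 0.03, and adjusted p = 0.925 with an estimated correlation). That list did not pass without TKO 1 or 2 (0.119 and 0.0555). Of 19 p53 targets 5 rose and 14 did not pass. Cdkn1a, the p21 cell cycle inhibitor, stood at 212 ± 36.0 against 115 ± 13.3 CPM (log2 fold change 0.84 ± 0.13, edgeR adjusted p = 0.00547), and Trp53inp1 and Bbc3 at log2 fold changes of 0.96 ± 0.11 and 1.4 ± 0.23. Adjusted over the list alone 7 rose (camera adjusted p = 0.00016, and adjusted p = 0.826 with an estimated correlation), and without TKO 3 the list did not pass (adjusted p = 0.073). Of 12 transcripts of the 2-cell stage 3 fell and 9 did not pass, 6 fell adjusted over the list alone, and the list was lower (median log2 fold change -1.95, camera adjusted p = 2.45e-05, and adjusted p = 0.826 with an estimated correlation). Among the largest changes were the rise of Dcdc2a and Crmp1, both known from neurons (log2 fold changes 4.51 ± 0.42 and 4.43 ± 0.55), and the fall of Nkx1-2, a homeobox gene (-3.16 ± 0.49). With edgeR's quasi-likelihood test over 14959 genes 1471 rose and 706 fell. The count of 2177 became 635, 740 and 574 without WT 1, 2 and 3, 866 without TKO 2, 6968 without TKO 3 and 1291 with TKO and WT alone in the fit. X-linked genes as a whole were lower than in WT in TKO 1 and 2 (median log2 shifts -0.79 and -0.50 over 584 genes) and near WT in TKO 3 (-0.02), and in STOP 1 and 2 the shifts were -0.58 and -0.45.

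STOP cells were compared with WT and with TKO, as a further Dnmt genotype. Dazl rose to 155 ± 11.8 CPM (log2 fold change 3.51 ± 0.22, edgeR adjusted p = 0.000345), Smc1b to 25.3 ± 9.52 CPM (2.39 ± 0.29). Plb1, a phospholipase gene, rose to 7.06 ± 1.29 from 0.112 ± 0.110 CPM (log2 fold change 5.90 ± 0.62, edgeR adjusted p = 0.00183). Of the 30 germ cell genes 13 rose and 17 did not pass, with 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.83e-05, and adjusted p = 0.826 with an estimated correlation). Of 15 maternally expressed genes of maternally methylated clusters 7 rose, and 8 adjusted over the list alone (median log2 fold change 0.87, camera adjusted p = 0.00628, and adjusted p = 0.826 with an estimated correlation). Grb10 stood at 116 ± 29.8 against 18.1 ± 4.54 CPM (log2 fold change 2.58 ± 0.33, edgeR adjusted p = 0.00338). Of 20 paternally expressed genes of such clusters 1 rose and 3 fell, in all and adjusted over the list alone (median -0.22, camera adjusted p = 0.308). Of 15 naive pluripotency genes 8 fell and 1 rose, and 9 and 1 adjusted over the list alone (median -0.64, camera adjusted p = 0.00243, and adjusted p = 0.835 with an estimated correlation). Klf4 had a log2 fold change of -0.96 ± 0.14 (edgeR adjusted p = 0.00544, and 0.0705 without STOP 2). Of 18 hypoxia and glycolysis genes 7 rose and 8 did so adjusted over the list alone (median 1.02, camera adjusted p = 9.27e-05, and adjusted p = 0.836 with an estimated correlation). In TKO cells 5 of the 18 rose, and 6 adjusted over the list alone (median 0.75, camera adjusted p = 0.00496, and adjusted p = 0.925 with an estimated correlation). There the list did not pass without TKO 2 (0.0705). The p53 targets passed in STOP cells too, with 5 of 19 risen, also adjusted over the list alone (median 0.48, camera adjusted p = 0.0144, and adjusted p = 0.87 with an estimated correlation). In all 3463 genes passed (2062 rose, 1401 fell), and 773, 1228 and 656 without WT 1, 2 and 3, 384 without STOP 1, 124 without STOP 2 and 8133 with STOP and WT alone in the fit.

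TKO and STOP changes overlapped: 1318 genes rose and 555 fell in both, and 1 gene went opposite ways. Independent lists of the same sizes would share 202.8 and 66.1 genes. The covariance of the log2 fold changes across genes was 0.676 against a mean of 0.0683 in 20 simulations of unchanged groups set against the same WT libraries, and the shared controls contribute the simulated part. The simulations hold no difference between cultures. A difference from WT that TKO and STOP cultures share apart from genotype would therefore also raise the covariance above them. Without WT 1, 2 and 3 the number of genes called in both became 513, 645 and 437, without TKO 2 and 3 it became 795 and 5970, and without STOP 1 and 2 it became 355 and 120. Set against TKO directly, STOP cells were higher in 6 genes and lower in 0 by edgeR (439 at an unadjusted p under 0.05, and 10 called by DESeq2 or without TKO 3). They were Dnmt1 (log2 fold change 2.99 ± 0.076, edgeR adjusted p = 3.5e-07), Dnmt3b (2.32 ± 0.11), Dnmt3a (2.25 ± 0.11), Nt5c, Plb1 and, chosen after its values were seen, Gm11694. Nt5c, a nucleotidase gene, stood at 46.9 ± 0.984 against 13.1 ± 0.678 CPM (log2 fold change 1.78 ± 0.14, edgeR adjusted p = 0.00132). Plb1 (edgeR adjusted p = 0.036) did not pass without TKO 2, STOP 1 or STOP 2 (0.184, 0.312 and 0.547) or in the fit of both genotypes alone (0.159). Transcripts of the 2-cell stage stood higher in STOP than in TKO, with 0 of 12 called, 4 adjusted over the list alone and a median log2 fold change of 1.75 (camera adjusted p = 1.28e-14, and adjusted p = 0.77 with an estimated correlation).

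Embryos labelled pIR were compared with pWT at 3 stages before implantation; the pWT columns of these stages carry another name in the deposited tables and were matched by stage and number. At the 2C stage edgeR called 0 of 11076 genes, with 235 at an unadjusted p under 0.05 and 8 called by DESeq2, and a simulated 4-fold change was recovered for 4.5% of genes. The p53 targets had a median log2 fold change of -0.75, with 4 of 14 members higher, 0 called and 0 called adjusted over the list alone (camera adjusted p = 0.0335, and adjusted p = 0.826 with an estimated correlation). The p53 target list did not pass without pWT 1, 2 or 4 (adjusted p = 0.0633, 0.298 and 0.0758) or pIR 3 or 4 (0.24 and 0.088). Meg3 had a log2 fold change of -0.40 ± 1.02 (edgeR adjusted p = 1).

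In morulae 5 genes rose and 11 fell, of 11773 tested. Rmi2, a subunit of the complex that dissolves DNA recombination intermediates (chromosome 16, 10835059–10892966), stood at 4.41 ± 2.07 against 59.3 ± 6.73 CPM (log2 fold change -3.59 ± 0.44, edgeR adjusted p = 0.0186). Bag1, an Hsp70 co-chaperone (chromosome 4, 40936398–40948294), stood at 56.3 ± 18.8 against 308 ± 86.1 CPM (log2 fold change -2.31 ± 0.28, edgeR adjusted p = 0.0186). For both, each pIR library lay below each pWT library. Spp1, which encodes the secreted protein osteopontin, was higher at 44.0 ± 42.0 against 0.834 ± 0.877 CPM (log2 fold change 6.01 ± 0.99, edgeR adjusted p = 0.0488). Rmi2 did not pass without pWT 1, pWT 2 or pIR 4 (adjusted p = 0.148, 0.0877 and 0.0794), and Bag1 not without pWT 1, pWT 2, pIR 2 or pIR 4 (0.0998, 0.0877, 0.0921 and 0.0794). Spp1 did not pass without any 1 of pWT 1, 2 and 3 (0.246, 0.126 and 0.119) or of pIR 1, 2, 3 and 4 (0.0879, 0.144, 0.0542 and 0.108). The number of genes called became 0, 0 and 6 without pWT 1, 2 and 3 and 8, 1, 7 and 0 without pIR 1, 2, 3 and 4. It was 335 with DESeq2, 58 with no filter on low counts, 218 with blastocysts in the same fit and 4 without the genes of chromosome 5. Genes of chromosome 5 were lower in pIR 1 (median log2 shift -0.96 over 739 genes), and 4 of the 16 called genes lie on it.

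In blastocysts 812 genes rose and 470 fell, of 12056 tested. Tcf15, a bHLH factor of epiblast cells leaving naive pluripotency (chromosome 2, 152143561–152149097), fell to 1.58 ± 0.530 from 21.3 ± 4.57 CPM (log2 fold change -3.55 ± 0.41, edgeR adjusted p = 0.00129). Bnip3, a hypoxia-induced mitophagy receptor (chromosome 7, 138890836–138909519), rose to 579 ± 99.2 from 279 ± 88.7 CPM (log2 fold change 1.24 ± 0.25, edgeR adjusted p = 0.0114). The 16 hypoxia and glycolysis genes did not pass as a list (median -0.08, camera adjusted p = 0.949), with 2 risen and 1 fallen. Id2, an inhibitor of bHLH factors that marks trophectoderm, rose to 2008 ± 504 from 893 ± 189.7 CPM (log2 fold change 1.34 ± 0.20, edgeR adjusted p = 0.00631). The 17 trophectoderm genes did not pass as a list (median log2 fold change 0.19, camera adjusted p = 0.518). Among them 2 rose and 1 fell, also adjusted over the list alone. Of 14 naive pluripotency genes 4 fell and 1 rose, and 8 fell and 2 rose adjusted over the list alone (median log2 fold change -0.73, camera adjusted p = 0.0112, and adjusted p = 0.77 with an estimated correlation). Of 10 genes imprinted through histone methylation 2 fell, and 3 adjusted over the list alone (median -0.70, camera adjusted p = 0.0134, and adjusted p = 0.826 with an estimated correlation). Jade1, a histone acetyltransferase cofactor among them, stood at 47.0 ± 12.7 against 115 ± 26.4 CPM (log2 fold change -1.12 ± 0.22, edgeR adjusted p = 0.0114). Id2 and Jade1 did not pass with morulae in the same fit (adjusted p = 0.117 and 0.0549). X-linked genes stood higher in every pIR than in every pWT library (median shifts 0.16 to 0.33 against -0.04 to 0.11 over 394 genes), and 13.5% of the X-linked and 6.5% of the autosomal genes tested rose. Plac1, an X-linked gene of the trophoblast, rose from 9.91 ± 11.5 to 118 ± 129 CPM (log2 fold change 3.76 ± 0.73, edgeR adjusted p = 0.0114) and did not pass without pWT 2 (0.0503). The count of 1282 became 417, 229 and 739 without pWT 1, 2 and 4 and 263 and 360 without pIR 2 and 3, against 2191 with DESeq2 and 584 with morulae in the fit. Fold changes followed transcript length and GC content in blastocysts (Spearman's rho -0.286 and -0.225) and in morulae (-0.237 and -0.167). No fit with these trends taken out was made for embryos. For the difference of the pIR effect between morulae and blastocysts edgeR called 0 genes, with 1101 at an unadjusted p under 0.05, 58 called by DESeq2 and 7, 9, 1 and 3 by edgeR without morula pWT 1, pWT 3, pIR 1 and pIR 2.

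Tissues labelled pTKO were compared with pWT at E18.5, and in each tissue germ cell genes stood higher. In brain 107 genes rose and 165 fell. Slc25a31, an ADP/ATP carrier of germ cells (chromosome 3, 40708855–40726096), stood at 9.40 ± 0.0142 against 0.518 ± 0.0598 CPM (log2 fold change 4.15 ± 0.34, edgeR adjusted p = 5.78e-05). Mael, a piRNA pathway gene, stood at 5.62 ± 2.01 against 0.198 ± 0.280 CPM (log2 fold change 4.66 ± 0.61, edgeR adjusted p = 0.00225). Ddx4, the germ cell RNA helicase Vasa, stood at 14.3 ± 0.773 against 4.02 ± 0.142 CPM (log2 fold change 1.82 ± 0.20, edgeR adjusted p = 0.000482). Of 15 germ cell genes 8 rose, and 9 adjusted over the list alone (camera adjusted p = 1.64e-19, and adjusted p = 0.77 with an estimated correlation). Dnmt1 and Dnmt3a fell (log2 fold changes -0.79 ± 0.059 and -0.69 ± 0.061, edgeR adjusted p = 4.26e-05 and 0.000115). The maternally expressed RNA Meg3 (chromosome 12, 109541001–109571726) stood at 5769 ± 82.6 against 4692 ± 364 CPM (log2 fold change 0.28 ± 0.056, edgeR adjusted p = 0.0293). Gfap, the astrocyte filament gene, rose (log2 fold change 1.61 ± 0.17, edgeR adjusted p = 0.000402) with 2 of the other 10 glial genes. Of these glial genes 7 rose adjusted over the list alone (camera adjusted p = 1.76e-09, and adjusted p = 0.826 with an estimated correlation). Of 8 erythroid genes 5 fell and 6 fell adjusted over the list alone (camera adjusted p = 1.75e-17, and adjusted p = 0.826 with an estimated correlation). The beta globin gene Hbb-bs, whose counts equal those of Hbb-b1 so that the copies cannot be told apart, stood at 203 ± 25.2 against 369.9 ± 35.5 CPM (log2 fold change -0.89 ± 0.084, edgeR adjusted p = 0.000167). Of 19 interferon-induced genes 1 rose and 12 adjusted over the list alone (median log2 fold change 0.88, camera adjusted p = 2.92e-12, and adjusted p = 0.77 with an estimated correlation). The brain count of 272 became 155 without pWT 1, 556 and 687 without pTKO 1 and 2, 951 with no filter on low counts and 99 with a transcript length trend taken out. With all 5 tissues in one fit 0 genes passed (Slc25a31 and Mael adjusted p = 0.78, and 1 for Ddx4, Dnmt1, Dnmt3a, Meg3, Gfap and Hbb-bs).

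In pTKO heart 2255 genes rose and 1787 fell. Meg3 rose to 515 ± 52.5 from 62.7 ± 2.34 CPM (log2 fold change 2.96 ± 0.14, edgeR adjusted p = 0.0165). Rian, of the same cluster (chromosome 12, 109603940–109661716), rose to 211 ± 2.78 from 54.7 ± 9.47 CPM (log2 fold change 1.86 ± 0.17, edgeR adjusted p = 0.0165). Dlk1, its paternally expressed gene for a Notch ligand-like growth regulator (chromosome 12, 109452823–109463336), fell to 29.8 ± 3.93 from 144 ± 41.5 CPM (log2 fold change -2.34 ± 0.21, edgeR adjusted p = 0.0165). H19 and Igf2 stood at log2 fold changes of -0.55 ± 0.15 (edgeR adjusted p = 0.0564) and -0.45 ± 0.12 (0.0492). Igf2 did not pass with all tissues in the fit (0.15), with a GC trend taken out (0.542) or without pTKO 1 or 2 (0.141 and 0.241). Of 22 germ cell genes 12 rose, and 14 rose and 1 fell adjusted over the list alone (median log2 fold change 2.57, camera adjusted p = 1.4e-05, and adjusted p = 0.835 with an estimated correlation). Slc25a31 stood at 35.3 ± 8.27 against 2.13 ± 1.6 CPM (log2 fold change 4.0 ± 0.54, edgeR adjusted p = 0.0196). Of 17 nuclear genes of the respiratory chain and its regulators 13 fell and 2 rose, with the same numbers adjusted over the list alone (median -0.57, camera adjusted p = 0.000854, and adjusted p = 0.92 with an estimated correlation). Cox4i1, a cytochrome oxidase subunit, fell to 1171 ± 27.6 from 1917 ± 32.2 CPM (log2 fold change -0.79 ± 0.11, edgeR adjusted p = 0.0194). The proliferation marker Mki67 rose (log2 fold change 2.78 ± 0.30, edgeR adjusted p = 0.0175) and so did Tet2, a methylcytosine dioxygenase (log2 fold change 2.17 ± 0.14, edgeR adjusted p = 0.0165). Mki67 did not stand for its list: 5 of 22 proliferation genes were higher, with 3 risen and 4 fallen, also adjusted over the list alone. The list did not pass (median -0.47, camera adjusted p = 0.475, and adjusted p = 0.963 with an estimated correlation). Every one of these calls was lost without pTKO 1 or pTKO 2, when edgeR called 0 genes. The adjusted p were then 0.102 and 0.114 for Meg3, Rian, Dlk1, Mki67 and Tet2, 0.105 and 0.121 for Slc25a31 and 0.114 and 0.121 for Cox4i1. The heart count was 4042, against 2300 with a GC trend taken out, and with that trend taken out the log2 fold change of Rian became 0.27 ± 0.18 (adjusted p = 0.338), that of Igf2 -0.11 ± 0.12 and that of Cox4i1 -0.42 ± 0.10 (0.0512), while Meg3 stayed at 2.98 ± 0.14 (0.0133). Fold changes followed GC content across genes (Spearman's rho -0.545), and Xist stood at 201 and 30.0 CPM in the pWT and at 1293 and 1297 CPM in the pTKO hearts.

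In pTKO kidney, liver and lung edgeR called 0 genes, with 2374, 642 and 488 at an unadjusted p under 0.05, 353, 60 and 13 called by DESeq2 and 6, 24 and 1 with all 5 tissues in one fit. Without pWT 1 edgeR called 5327 genes in kidney and 7191 in liver, without pWT 2 it called 945 and 458, and in lung it called 836 and 7876 without pTKO 1 and 2. Germ cell genes stood higher in kidney, with 0 of 18 called, 9 adjusted over the list alone and a median log2 fold change of 2.56 (camera adjusted p = 8.6e-18, and adjusted p = 0.826 with an estimated correlation). In liver 0 of 16 were called and 8 adjusted over the list alone, with a median of 2.26 (camera adjusted p = 3.88e-16, and adjusted p = 0.77 with an estimated correlation). In lung 0 of 17 were called and 2 adjusted over the list alone, with a median of 1.01 (camera adjusted p = 1.55e-09, and adjusted p = 0.77 with an estimated correlation). Slc25a31 stood at 17.0 ± 9.01 against 0.268 ± 0.258 CPM in kidney (edgeR adjusted p = 0.346) and at 10.3 ± 6.58 against 0.312 ± 0.137 CPM in liver (0.621). Mael stood at 3.60 ± 1.08 against 0.116 ± 0.107 CPM in lung (0.804). Meg3 had log2 fold changes of 1.68 ± 0.15, 1.93 ± 0.57 and 0.68 ± 0.71 in kidney, liver and lung (edgeR adjusted p = 0.346, 0.621 and 0.806). Dlk1 stood at 86.2 ± 19.6 against 314 ± 6.16 CPM in liver (0.621). Other lists passed in these tissues too, with 0 members called. In kidney the endothelial, myeloid and nephron lists were lower (medians -0.43, -0.99 and -0.47, camera adjusted p = 0.00532, 0.00363 and 0.0251). In liver all 23 interferon-induced genes were higher and all 12 myeloid genes lower (medians 0.95 and -0.77, camera adjusted p = 3.71e-07 and 0.000489). With an estimated correlation none of these passed (adjusted p = 0.826, 0.92, 0.826, 0.835 and 0.92), and the myeloid list did not pass without pWT 2 in kidney or liver (0.813 and 0.44), nor the nephron list without pTKO 2 (0.183). In lung, by camera, the neuron and glia lists were lower and the myeloid list higher, and none passed with an estimated correlation. Fold changes followed GC content in kidney, liver and lung (Spearman's rho -0.415, -0.487 and 0.446) and transcript length in lung (-0.456). Xist stood apart in pWT 2 of kidney (106 CPM) and liver (16.0 CPM) and in pTKO 1 of lung (92.0 CPM).

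**Figure D2:**
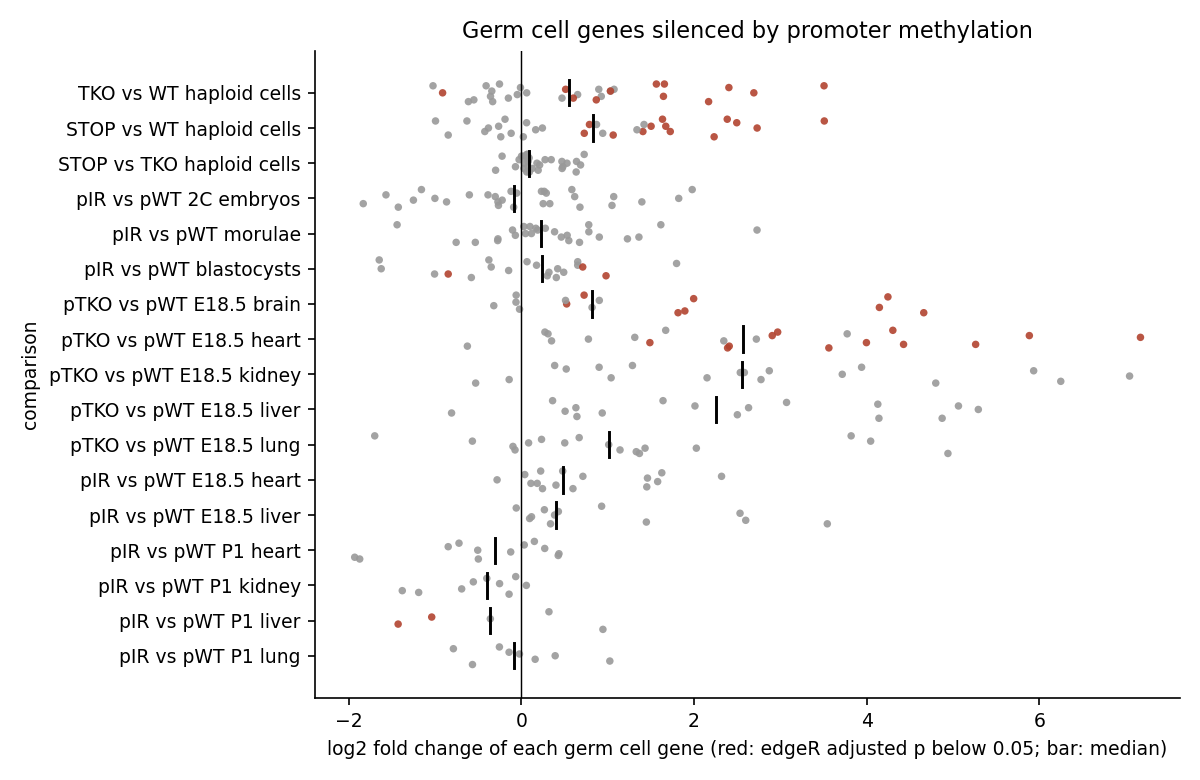
Log2 fold change of each measured germ cell gene in each comparison, 1 point per gene, with a bar at the median of the list and red points where edgeR adjusted p is under 0.05. The medians lie at 2.57, 2.56 and 2.26 in pTKO heart, kidney and liver, at 0.82 and 1.01 in pTKO brain and lung and at 0.48 and 0.41 in pIR E18.5 heart and liver.

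At E18.5 pIR heart and liver were compared with the pWT of their own batch. In heart 2 genes rose and 0 fell by edgeR (863 at an unadjusted p under 0.05, and 20 called by DESeq2), both on chromosome 11. Slc16a3, the lactate exporter MCT4 (chromosome 11, 120948480–120960868), rose to 149 ± 13.2 from 82.9 ± 8.60 CPM (log2 fold change 0.86 ± 0.083, edgeR adjusted p = 0.0106) with each pIR above each pWT library. Sectm1a, chosen after its values were seen, had no count in any pWT library (edgeR adjusted p = 0.0143). Slc16a3 did not pass without pWT 4 or pIR 4 (adjusted p = 0.057 and 0.0836) or with liver in the fit (0.208). The heart count became 0 without pWT 4 or pIR 4 and 1 without pIR 1, 2 or 3 or with liver in the fit. In liver edgeR called 0 genes (813 at an unadjusted p under 0.05, and 11 called by DESeq2), 2 without pIR 1 or 3, 2 with no filter on low counts and 1 with heart in the fit. Immediate early genes, which also respond to dissection, stood higher in both tissues. In heart 0 of 18 were called and 14 adjusted over the list alone (median log2 fold change 0.98, camera adjusted p = 4.55e-25, and adjusted p = 0.77 with an estimated correlation). In liver 0 of 16 were called and 7 adjusted over the list alone (median 0.56, camera adjusted p = 1.36e-16, and adjusted p = 0.77 with an estimated correlation). Nr4a1, an early response nuclear receptor, stood at 99.1 ± 53.1 against 28.8 ± 10.6 CPM in heart and 5.05 ± 2.18 against 1.87 ± 0.598 CPM in liver (edgeR adjusted p = 0.488 and 0.691). Other lists passed by camera too. In heart interferon-induced genes were lower and cardiomyocyte genes higher, and neither list passed without pWT 1 (camera adjusted p = 0.115 and 0.217). In liver matrix genes were higher and erythroid genes lower. The matrix list did not pass without pWT 1 or 3 (camera adjusted p = 0.283 and 0.149), nor the erythroid list without pWT 2 (0.17).

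Germ cell genes had lower medians in pIR than in pTKO tissues, each against the pWT of its own batch, and this difference between lists was not tested. In heart 0 of 15 were called and 3 adjusted over the list alone (median log2 fold change 0.48, camera adjusted p = 3.64e-06, and adjusted p = 0.826 with an estimated correlation). In liver 0 of 12 were called and 5 adjusted over the list alone (median 0.41, camera adjusted p = 3.34e-06, and adjusted p = 0.826 with an estimated correlation). Set against the batch 2 pWT libraries, the pTKO medians were 0.855 in heart and 1.063 in liver, below the 2.57 and 2.26 against batch 1 pWT. Part of the difference between pTKO and pIR may therefore come from the batch 1 controls. Slc25a31 stood at 21.8 ± 18.6 against 4.42 ± 2.65 CPM in pIR heart (edgeR adjusted p = 0.731). Meg3 and Dlk1 in pIR heart had log2 fold changes of 0.25 ± 0.19 and -0.72 ± 0.21 (edgeR adjusted p = 0.841 and 0.818). Set against each other, the pTKO and pIR effects in heart differed for 5918 genes, 3308 higher and 2610 lower in pTKO. Meg3 was among them, with a difference of log2 fold changes of 2.71 ± 0.33 (edgeR adjusted p = 6.95e-05), as was Dlk1 (-1.62 ± 0.37, edgeR adjusted p = 0.0044). Against batch 2 pWT, Meg3 in the pTKO hearts had a log2 fold change of 1.16 ± 0.15, smaller than against batch 1 pWT. In liver the effects differed for 6 genes by edgeR and 565 by DESeq2, among them Dlk1 (-1.94 ± 0.25, edgeR adjusted p = 0.0439) and Dnmt1 (-1.09 ± 0.12, edgeR adjusted p = 0.0103). The liver count became 6993 and 41 without batch 1 pWT 1 and 2, 2 and 1 without pTKO 1 and 2, 2, 1, 2 and 2 without batch 2 pWT 1, 2, 3 and 4 and 3, 3 and 2 without pIR 1, 2 and 3. Dlk1 in liver did not pass without pTKO 1 or 2 (adjusted p = 0.0604 and 0.253), batch 2 pWT 1, 2, 3 or 4 (0.0991, 0.132, 0.0687 and 0.0924) or pIR 1, 2 or 3 (0.0733, 0.11 and 0.103), and Dnmt1 not without pTKO 1 or 2 (0.0604 and 0.139) or batch 2 pWT 2 (0.0587). Genotype and batch change together here, so a batch effect on one genotype cannot be told apart from the genotype. The pIR effect differed between heart and liver for 1 gene, Sectm1a (edgeR adjusted p = 0.00192, with 848 at an unadjusted p under 0.05, 3 called by DESeq2 and 2 by edgeR without liver pIR 3).

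**Figure D3:**
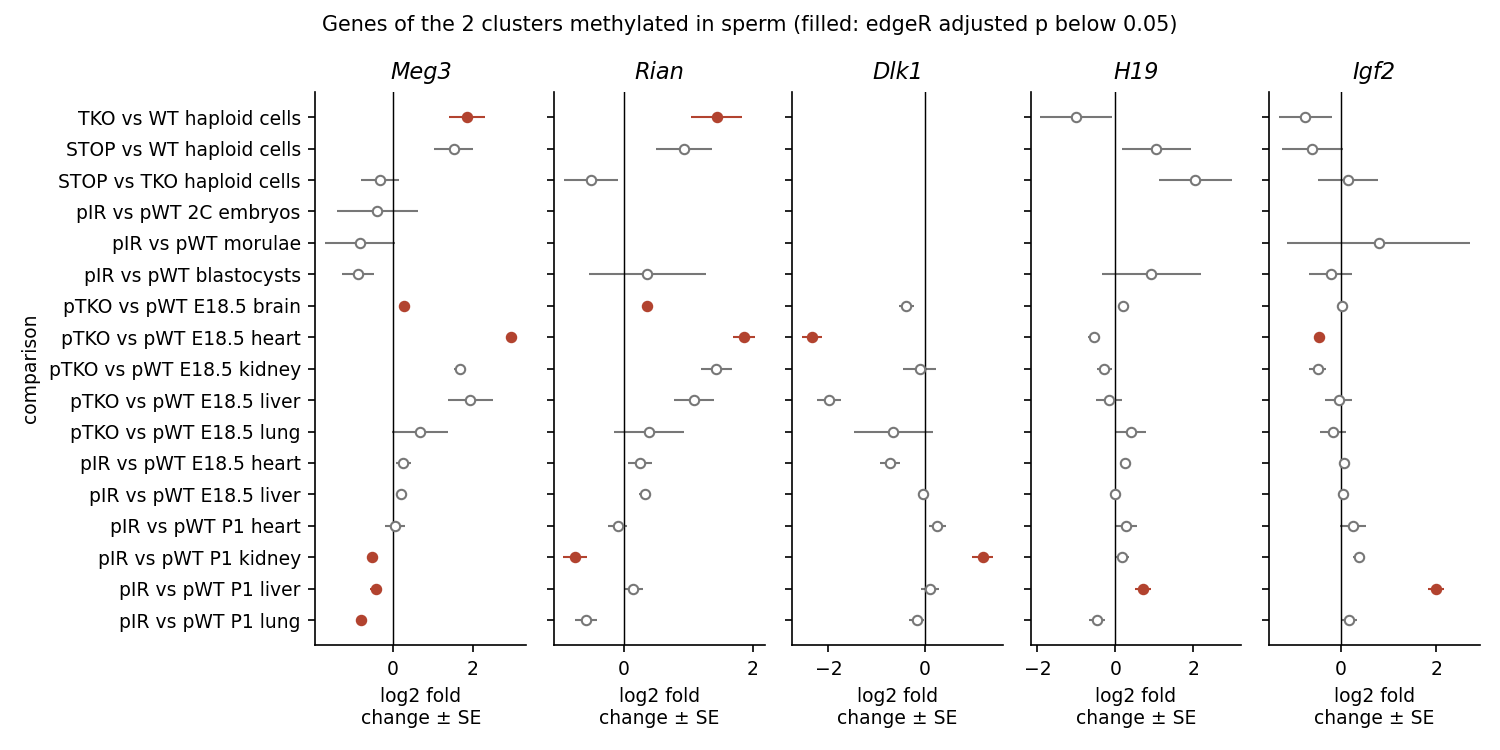
Log2 fold change ± SE of Meg3, Rian, Dlk1, H19 and Igf2 in each comparison, with filled points where edgeR adjusted p is under 0.05. Meg3 lies at 2.96 and Dlk1 at -2.34 in pTKO heart, and Igf2 at 1.99 in pIR P1 liver.

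At P1 pIR tissues were compared with pWT after birth, with 2 pIR libraries per tissue. In heart Dlgap1, a postsynaptic scaffold gene (chromosome 17, 69969073–70821413), rose to 98.3 ± 23.5 from 0.211 ± 0.188 CPM (log2 fold change 8.71 ± 0.43, edgeR adjusted p = 0.000698). Rbp7, a retinol-binding protein (chromosome 4, 149449687–149454978), fell to 17.5 ± 4.61 from 125 ± 9.37 CPM (log2 fold change -2.93 ± 0.21, edgeR adjusted p = 0.00327). Timp4, a metalloproteinase inhibitor (chromosome 6, 115241892–115252205), fell to 7.31 ± 0.957 from 45.3 ± 6.88 CPM (log2 fold change -2.72 ± 0.19, edgeR adjusted p = 0.00327). Of 12 fibroblast and matrix genes 5 rose and 10 adjusted over the list alone (median log2 fold change 0.88, camera adjusted p = 1.21e-09, and adjusted p = 0.826 with an estimated correlation). The collagen gene Col1a1, in a run of higher genes on chromosome 11 described with the lung, stood at 2586 ± 729 against 922 ± 163 CPM (log2 fold change 1.39 ± 0.24, edgeR adjusted p = 0.0421). Of 11 erythroid genes 4 fell and 8 adjusted over the list alone (median -0.92, camera adjusted p = 1.98e-08, and adjusted p = 0.77 with an estimated correlation). Of 12 hepatocyte genes 4 fell and 7 adjusted over the list alone (median -2.40, camera adjusted p = 2.77e-12, and adjusted p = 0.77 with an estimated correlation). Albumin (Alb) stood at 2.36 ± 0.0570 against 29.5 ± 4.49 CPM (log2 fold change -3.74 ± 0.24, edgeR adjusted p = 0.00291) and did not pass with all tissues in the fit (0.0518). Of 17 respiratory chain genes 2 fell and 7 adjusted over the list alone (median -0.45, camera adjusted p = 6.76e-06, and adjusted p = 0.835 with an estimated correlation). Cardiomyocyte markers moved the same way as a list: of 16 genes 13 were lower, with 1 fallen and 1 risen, and 1 and 2 adjusted over the list alone (median -0.45, camera adjusted p = 0.0371, and adjusted p = 0.835 with an estimated correlation). The cardiomyocyte list did not pass without pWT 2 or pIR 2 (adjusted p = 0.0665 and 0.385). Of 18 immediate early genes 0 were called and 8 rose adjusted over the list alone (median 0.64, camera adjusted p = 3.59e-05, and adjusted p = 0.826 with an estimated correlation). The atrial myosin light chain Myl7 stood at 2068 ± 2388 against 104 ± 29.5 CPM (log2 fold change 4.19 ± 0.78, edgeR adjusted p = 0.0433) and differed between the pIR libraries by more than its mean. Col1a1 and Myl7 did not pass without pWT 1, 2 or 3 (0.0824, 0.0964 and 0.171, and 0.096, 0.105 and 0.171) or pIR 2 (0.177 and 0.107). Of 15021 genes 231 rose and 118 fell. The count of 349 became 44, 5 and 5 without pWT 1, 2 and 3, 1162 and 6 without pIR 1 and 2, 1107 with no filter on low counts, 2629 with all tissues in the fit and 1601 with DESeq2.

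In P1 kidney Miox, the tubular enzyme that starts inositol breakdown (chromosome 15, 89334398–89337015), rose to 111 ± 1.67 from 3.11 ± 1.28 CPM (log2 fold change 5.19 ± 0.25, edgeR adjusted p = 0.000409). Kap, an androgen-regulated tubular gene, rose to 939 ± 113 from 114 ± 69.2 CPM (log2 fold change 3.09 ± 0.40, edgeR adjusted p = 0.00681). Ren1, the renin gene, rose to 592 ± 25.3 from 20.7 ± 14.5 CPM (log2 fold change 4.89 ± 0.62, edgeR adjusted p = 0.0066). Strains differ in a near-identical copy, Ren2, and how such reads were assigned is not given in the sources used here. Of 14 nephron genes 7 rose and 2 fell, and 8 and 3 adjusted over the list alone (median log2 fold change 1.26, camera adjusted p = 0.00269, and adjusted p = 0.826 with an estimated correlation). Of 17 genes of fatty acid oxidation and ketone synthesis 10 rose and 14 adjusted over the list alone (camera adjusted p = 1.21e-11, and adjusted p = 0.826 with an estimated correlation). They included carnitine palmitoyltransferase Cpt2 (log2 fold change 1.13 ± 0.10) and the lipase inhibitor Angptl4 (1.37 ± 0.14). Of 17 hepatocyte genes 5 rose and 7 adjusted over the list alone (camera adjusted p = 3.18e-07, and adjusted p = 0.826 with an estimated correlation). The gluconeogenic G6pc, which kidney also expresses, was 1 of them (log2 fold change 3.26 ± 0.44, edgeR adjusted p = 0.00755). Matrix genes rose too, 6 of 12 and 8 adjusted over the list alone (camera adjusted p = 1.33e-05, and adjusted p = 0.826 with an estimated correlation), with Col1a1, of the same chromosome 11 run, at 1558 ± 144 against 788 ± 45.8 CPM. All 11 endothelial genes were higher, and 4 rose and 7 adjusted over the list alone (median 0.39, camera adjusted p = 0.000368, and adjusted p = 0.826 with an estimated correlation). In the Meg3 cluster Dlk1 rose (log2 fold change 1.2 ± 0.22, edgeR adjusted p = 0.0179) and Meg3 fell (log2 fold change -0.53 ± 0.13, edgeR adjusted p = 0.0419). Dlk1 did not pass without pWT 1 or pIR 1 (0.0746 and 0.119), and Meg3 not without pWT 1, pWT 2, pIR 1 or pIR 2 (0.132, 0.0948, 0.171 and 0.0626) or with all tissues in the fit (0.121). Of 16234 genes 1230 rose and 497 fell. The count of 1727 became 150 and 1089 without pWT 1 and 2, 348 without pIR 1 and 2764 with DESeq2.

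In P1 liver 3018 genes rose and 2694 fell, of 14588 tested. Igf2, the fetal growth factor (chromosome 7, 142650766–142666816), rose to 10490 ± 126 from 3349 ± 150.3 CPM (log2 fold change 1.99 ± 0.17, edgeR adjusted p = 5.54e-06). Afp, the fetal serum protein gene (chromosome 5, 90490737–90508907), rose to 21370 ± 1771 from 5057 ± 696 CPM (log2 fold change 2.42 ± 0.19, edgeR adjusted p = 3.83e-06). Of 17 hepatocyte genes 16 rose, in all and adjusted over the list alone (median log2 fold change 1.02, camera adjusted p = 5.71e-09, and adjusted p = 0.826 with an estimated correlation). The thyroid hormone carrier Ttr was 1 of them (log2 fold change 1.43 ± 0.16, edgeR adjusted p = 2.77e-05). Of 17 genes of fatty acid oxidation and ketone synthesis 14 rose and 1 fell, in all and adjusted over the list alone (median 1.2, camera adjusted p = 3.83e-11, and adjusted p = 0.77 with an estimated correlation). Cpt2 rose to 191 ± 5.78 from 62.4 ± 7.29 CPM (log2 fold change 1.95 ± 0.14, edgeR adjusted p = 2.1e-06). The lipid droplet gene Plin2 rose (log2 fold change 1.99 ± 0.19, edgeR adjusted p = 1.22e-05), and so did Fgf21, a fasting hormone of the liver (log2 fold change 3.70 ± 0.52, edgeR adjusted p = 0.000171). Of 16 erythroid genes 14 fell and 15 adjusted over the list alone (median -1.21, camera adjusted p = 1.62e-09, and adjusted p = 0.826 with an estimated correlation). Haemoglobin genes took 8.85%, 7.69% and 9.75% of the counts in pWT 1, 2 and 3 and 3.39% and 2.27% in pIR 1 and 2. Of 22 proliferation genes 17 fell and 18 adjusted over the list alone (median -0.71, camera adjusted p = 1.22e-07, and adjusted p = 0.826 with an estimated correlation). Mki67 stood at 56.4 ± 7.69 against 236 ± 30.5 CPM (log2 fold change -1.72 ± 0.17, edgeR adjusted p = 1.39e-05). Markers of other cells moved apart: the macrophage genes Adgre1 and Csf1r rose (log2 fold changes 1.56 ± 0.16 and 1.03 ± 0.14) and the neutrophil genes Elane and S100a8 fell (-1.0 ± 0.16 and -0.96 ± 0.17). The count of 5712 stayed between 4325 and 5139 without any 1 library.

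**Figure D4:**
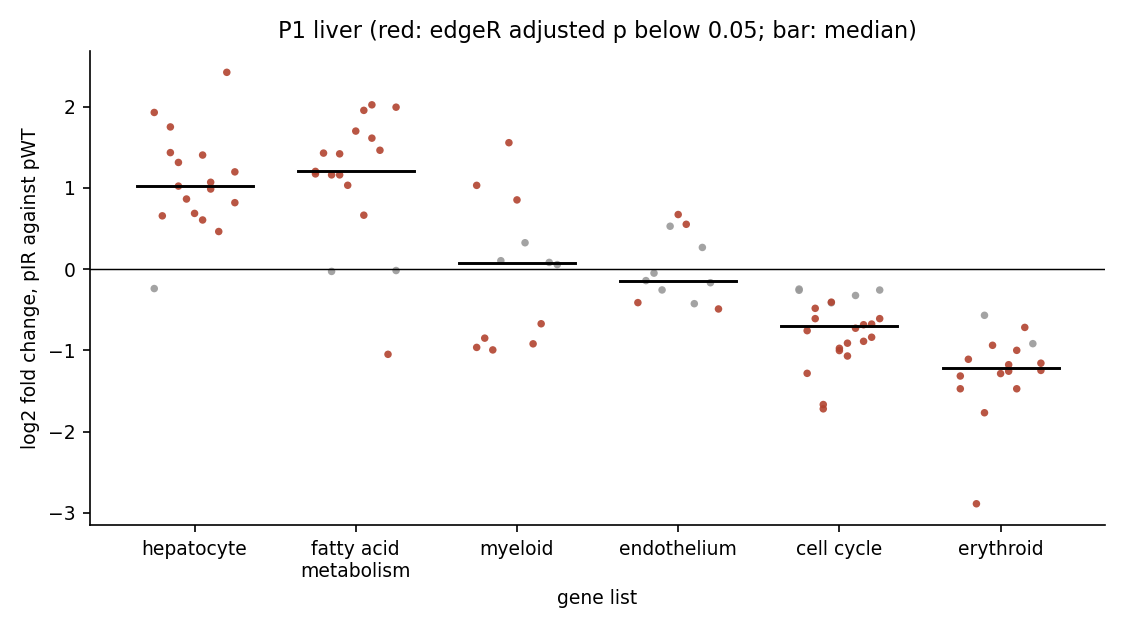
Log2 fold change of each measured gene of 6 gene lists in P1 liver, pIR against pWT, 1 point per gene with a bar at the median. Hepatocyte and fatty acid genes have medians of 1.02 and 1.2, erythroid and proliferation genes of -1.21 and -0.71, and endothelial genes of -0.14.

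Of 18 paternally expressed genes of maternally methylated imprinted clusters 5 rose and 4 fell in P1 liver, in all and adjusted over the list alone (median log2 fold change -0.03, camera adjusted p = 0.899, and adjusted p = 0.963 with an estimated correlation). Peg10, a retrotransposon-derived gene among them, rose to 102 ± 0.766 from 29.7 ± 6.37 CPM (log2 fold change 2.12 ± 0.16, edgeR adjusted p = 2.94e-06). Of 18 maternally expressed genes of the same kind of cluster 8 rose and 1 fell, and 9 and 1 adjusted over the list alone (median 0.40, camera adjusted p = 0.0335, and adjusted p = 0.826 with an estimated correlation), and the list did not pass without pIR 1 or 2 (0.0606 and 0.0723). Igf2r, 1 of them, rose (log2 fold change 1.24 ± 0.12, edgeR adjusted p = 1.49e-05), as did Gpc3, an X-linked glypican that limits growth (log2 fold change 1.81 ± 0.15, edgeR adjusted p = 4.22e-06). Of 19 fetal growth genes 10 rose and 2 fell, and 11 and 3 adjusted over the list alone (median log2 fold change 0.40, camera adjusted p = 0.0128, and adjusted p = 0.835 with an estimated correlation). H19, which shares a control region with Igf2 and is expressed from the other parental copy, stood at 22650 ± 890.4 against 17700 ± 3213 CPM (log2 fold change 0.70 ± 0.21, edgeR adjusted p = 0.0194). Meg3 stood at 71.2 ± 0.221 against 123 ± 9.71 CPM (log2 fold change -0.44 ± 0.13, edgeR adjusted p = 0.0207). CPM are not scaled by TMM, so in this tissue the ratio of CPM differs from the fitted fold. H19 did not pass without pWT 1, pWT 3 or pIR 2 (0.103, 0.0894 and 0.092) or with all tissues in the fit (0.0605). Meg3 did not pass without pWT 2, pWT 3 or pIR 1 (0.0638, 0.102 and 0.0721) or with all tissues in the fit (0.111).

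In P1 lung 247 genes rose and 174 fell, of 16203 tested. Selenbp2, a selenium-binding protein gene (chromosome 3, 94693556–94704413), fell to 2.66 ± 0.0676 from 56.6 ± 19.8 CPM (log2 fold change -4.45 ± 0.34, edgeR adjusted p = 0.00295). Nmnat1, an NAD synthesis enzyme of the nucleus (chromosome 4, 149467572–149485202), fell to 8.08 ± 0.256 from 31.5 ± 1.11 CPM (log2 fold change -2.00 ± 0.12, edgeR adjusted p = 0.000975). For both, each pIR library lay below each pWT library. Of 12 fibroblast and matrix genes 3 rose and 1 fell, and 7 and 1 adjusted over the list alone (median log2 fold change 0.50, camera adjusted p = 0.000408, and adjusted p = 0.826 with an estimated correlation). Col1a1 stood at 2465 ± 451 against 1163 ± 200.2 CPM (log2 fold change 1.05 ± 0.15, edgeR adjusted p = 0.0144). Of 15 erythroid genes 4 fell and 6 adjusted over the list alone (median -0.35, camera adjusted p = 2.14e-05, and adjusted p = 0.826 with an estimated correlation). Of 18 immediate early genes 1 rose and 6 adjusted over the list alone (median 0.39, camera adjusted p = 0.00444, and adjusted p = 0.826 with an estimated correlation), and the list did not pass without pWT 2 (0.065). Of 22 proliferation genes 1 rose and 9 adjusted over the list alone (median 0.40, camera adjusted p = 2.92e-06, and adjusted p = 0.831 with an estimated correlation). Of the 4 maternally expressed genes of paternally methylated clusters, Meg3 fell to 306 ± 46.6 from 520 ± 88.0 CPM (log2 fold change -0.80 ± 0.14, edgeR adjusted p = 0.0284). All 4 fell adjusted over the list alone (median -0.69, camera adjusted p = 0.000368, and adjusted p = 0.77 with an estimated correlation). Meg3 did not pass without pIR 1 or 2 (0.107 and 0.255) or with all tissues in the fit (0.0753). Col1a1 did not pass without pWT 3, pIR 1 or pIR 2 (0.0515, 0.0576 and 0.139) or with all tissues in the fit (0.0753). The count of 421 became 226 without pWT 3, 18 and 26 without pIR 1 and 2, 708 with no filter on low counts, 148 with all tissues in the fit and 1085 with DESeq2. Col1a1 lies in a run of 25 neighbouring genes of chromosome 11 (94936224–96354691) with median log2 fold changes of 0.84, 0.70, 0.29 and 0.45 in pIR heart, kidney, liver and lung, where 88%, 96%, 56% and 96% of its genes were higher. A run of 25 genes of chromosome 4 (117884326–119422420), which holds Cdc20 of the proliferation list and Ermap of the erythroid list, had medians of -0.62, -0.45, -0.78 and -0.54.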

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

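The tests of the GC content trend, of blood cell share, of haemoglobin and of Meg3 against batch 2 in this part were chosen only after the result was seen; the splits of the libraries and the other comparisons with batch 2 were planned.

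Among 36 sets of 4 values, 2 held a library far from the others, where chance gives about 1 in 20. The total count of 2C pIR 3 was 6136789, with the other 3 between 7406038 and 7548315, and that of blastocyst pIR 1 was 11578369, with the others between 9787645 and 9958605. Effects differed between groups in 3 tests: the pIR effect between E18.5 heart and liver for 1 gene, and the pTKO and pIR effects for 5918 genes in heart and 6 in liver.

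Other splits of the same libraries were set against the real split. In morulae the real split called 16 genes and the highest other split 1, and in blastocysts 1282 and 1. In each 1 of 35 splits was as high, the lowest share possible, which argues against chance as the source of both counts without excluding it. A difference between the groups other than genotype would give the same result. Chance is not argued against for pIR E18.5 heart (2 called, 10 in the highest other split, 2 of 35 as high), nor for the difference of the pIR effect between heart and liver (1 called, 13 in the highest other, 17 of 100 as high). For 2C embryos (0 called by edgeR, 235 at an unadjusted p under 0.05 and 8 by DESeq2; 0 in the highest other split) and pIR E18.5 liver (0 by edgeR, 813 and 11; 2) all 35 splits were as high, as any split must be where 0 genes were called, so the splits decide nothing there. For TKO against WT the 10 splits are too few for a share under 0.05, with 2177 genes called and 0 in the highest other split, 1 of 10 as high. The difference of the pIR effect between morulae and blastocysts (0 called by edgeR, 1101 at an unadjusted p under 0.05 and 58 by DESeq2) was matched by all 100 splits for the same reason. Another split called 64 genes, which points to a structure of the samples: it kept the morula labels and changed 6 blastocyst labels, so the genotype effects themselves may give those calls.

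The many genes called in pTKO E18.5 heart were weighed against a pair of technical explanations. A GC content trend as the whole cause is argued against, since 2300 genes were called with the trend taken out and 1526 of the 4042 calls held, but 209 of the 4042 genes changed direction, so the trend may act on part of them. The batch 1 pWT hearts may stand apart: against the pWT hearts of batch 2 they differed in 10012 of 15454 genes, 1.67 times the 5985 of the pTKO hearts. Part of the heart calls may therefore reflect the control libraries, and since only batch 1 holds pTKO, this cannot be separated from genotype for a single gene.

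The higher germ cell genes and Meg3 of the pTKO tissues were weighed in the same way. With the GC content trend taken out, the list medians were 0.825, 2.44, 2.19, 2.01 and 1.16 in brain, heart, kidney, liver and lung (lowest 0.825), so the trend is argued against for the germ cell genes. Meg3 in heart stayed at 2.975 (2.959 before), but Rian of the same cluster fell from 1.864 to 0.268 in heart, from 1.438 to 0.049 in kidney and from 1.091 to -0.411 in liver, so its rise there may follow from the trend. Against the pWT libraries of batch 2 the germ cell median of the pTKO libraries was 0.855 in heart and 1.063 in liver (1.418 and 1.133 with the GC content trend of that comparison taken out), and the batch 1 pWT libraries lay at -0.86 and -0.79. Control libraries that stand apart are therefore argued against as the whole cause for germ cell genes in heart and liver, but the medians against batch 1 pWT were larger (2.57 and 2.26), so they may account for part. Meg3 in the pTKO libraries stood 1.157 ± 0.154 above batch 2 pWT in heart (edgeR adjusted p = 0.00107), which goes the same way. However, 5985 of 15454 genes passed in that contrast across batches, so a pass of 1 gene weighs little there. For Meg3 in liver the difference of 0.664 ± 0.347 (0.217) decides nothing. Brain, kidney and lung have no second set of controls, and a batch difference cannot be told apart from genotype, as only batch 1 holds pTKO. Loss of DNA methylation on the paternal genome stays a candidate explanation, and methylation was not measured here.

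For P1 liver, higher hepatocyte and lower erythroid genes might follow from a lower share of blood-forming cells alone. That would raise every other cell type alike, and the endothelial genes had a median log2 fold change of -0.142 against a lower quartile of 0.685 for the hepatocyte genes, so it is argued against as the whole cause. Haemoglobin taking a share of the counts is argued against as well: the lower share can raise the CPM of every other gene by a log2 of at most 0.115, and the hepatocyte genes had a lower quartile of 0.334 and a median of 0.672 on that scale. A difference in developmental timing or nutrition between the newborns stays open and was not tested.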

How the results depend on the processing

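The fits with GC content or transcript length taken out, without haemoglobin, chromosome 5 or chromosome X genes, with crossed numbers and all alternatives of the overlap and GC trend for lists were chosen only after the result was seen; the others were planned. Median-of-ratios scaling left every count of genes within 1.5 times its value except the morula and blastocyst difference (0 to 1). For the 466 called named genes, 4414 of 5594 values under alternatives kept direction and call, 1178 kept direction only and 2 reversed: Cd36 (-0.45) and Klf6 (-0.11) in pTKO heart with the GC content trend taken out. In all 135 genes kept their call throughout and 303 lost it without 1 library. Where that leaves 1 library in a group, its spread is taken from the other group. The cause was not tested for any change below.

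With DESeq2 the counts became 10 in STOP against TKO, 8 in 2C embryos, 335 in morulae, 2191 in blastocysts, 353, 60 and 13 in pTKO kidney, liver and lung, 20 and 11 in pIR E18.5 heart and liver, and 1601, 2764 and 1085 in P1 heart, kidney and lung. For the differences of effects it gave 3 (pIR, heart and liver), 58 (morulae and blastocysts) and 565 (pTKO and pIR, liver). With no filter on low counts they became 58 in morulae, 951 in pTKO brain, 2 in pIR E18.5 liver, 1107 and 708 in P1 heart and lung and 3 for morulae and blastocysts. With other libraries in the fit they became 1291 for TKO and 8133 for STOP (only the genotypes compared), 218 in morulae and 584 in blastocysts (both stages), 0, 6, 24 and 1 in pTKO brain, kidney, liver and lung, 1 and 1 in pIR E18.5 heart and liver, and 2629 and 148 in P1 heart and lung (all tissues). The GC content trend taken out gave 2300 in pTKO heart, the length trend taken out 99 in pTKO brain, and leaving out chromosome 5 gave 4 in morulae. Gene lists passing fell from 104 to 0 with an estimated correlation and to 7 with fry, 5 of them among the 104.

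The labels tie no replicate number to an animal or day. Correlations of same-numbered libraries ran from -0.342 to 0.195, and in no comparison with 3 or more pairs did every library correlate best with its own number. With 2 pairs both did so in STOP against WT (0.088 and 0.125), pTKO brain (0.011), pTKO lung (0.171) and P1 lung (0.195 and 0.186), too few pairs to decide. As a block the number gave 1 gene in morulae (16 without it), 168 in pTKO brain (272), 2535 in pTKO heart (4042), 9 in pTKO lung (0), 0 in pIR E18.5 heart (2), 4 in pIR E18.5 liver (0), 56 in P1 heart (349) and 1209 in P1 lung (421), and stayed within 1.5 times elsewhere. Crossed numbers gave 3034, 0 and 0 genes in pTKO heart, kidney and liver.

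Without 1 library the counts ranged from 574 to 6968 for TKO, 124 to 1228 for STOP, 4 to 10 for STOP against TKO, 0 to 0 in 2C embryos, 0 to 8 in morulae and 229 to 1520 in blastocysts. In pTKO brain, heart, kidney, liver and lung they ranged from 155 to 687, 0 to 5266, 0 to 5327, 0 to 7191 and 0 to 7876, in pIR E18.5 heart and liver from 0 to 3 and 0 to 2, and in P1 heart, kidney, liver and lung from 5 to 1162, 150 to 2219, 4325 to 5139 and 18 to 346. For differences of effects they ranged from 1 to 2 (pIR, heart and liver), 0 to 9 (morulae and blastocysts), 4805 to 6092 (pTKO and pIR, heart) and 1 to 6993 (liver), and for genes called in both TKO and STOP from 120 to 5970. A simulated 4-fold change was recovered for 0% of genes in pTKO liver and 4.5% in 2C embryos, so counts of 0 there exclude little. Depth alone does not set this: pTKO and pWT libraries held 21.7 to 24.4 M counts in liver and 10.7 to 16.2 M in brain, where 93.9% were recovered.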

Other observations

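The tests of X dosage, of a missing chromosome copy or segment and of permuted gene orders in this part were chosen only after the result was seen; the comparisons behind the fold changes and adjusted p, and leaving out each library, were planned.

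Several genes moved alike in morulae and blastocysts, and their blastocyst values were looked up after the morula calls were known. Rmi2 stood at 10.9 ± 7.07 against 55.3 ± 2.65 CPM in pIR against pWT blastocysts (log2 fold change -2.13 ± 0.37, edgeR adjusted p = 0.00909) and Bag1 at 78.5 ± 20.4 against 385 ± 149 CPM (log2 fold change -2.13 ± 0.29, edgeR adjusted p = 0.00474), each pIR library below each pWT library. Spp1 stood at 1383 ± 205 against 509.6 ± 171 CPM (log2 fold change 1.63 ± 0.25, edgeR adjusted p = 0.00713), each pIR above each pWT library. Calls without 1 library were not computed for these genes in blastocysts. Meg3 fell in P1 kidney, liver and lung, with log2 fold changes of -0.53 ± 0.13, -0.44 ± 0.13 and -0.80 ± 0.14, and stood at 0.04 ± 0.26 in P1 heart (edgeR adjusted p = 0.937), while the same gene stood higher in pTKO heart and brain. Each of the 3 P1 calls was lost without at least 1 library: without pWT 1, pWT 2, pIR 1 or pIR 2 in kidney (adjusted p = 0.132, 0.0948, 0.171 and 0.0626), without pWT 2, pWT 3 or pIR 1 in liver (0.0638, 0.102 and 0.0721) and without pIR 1 or pIR 2 in lung (0.107 and 0.255).

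Clustered protocadherins were measured together: 22 of 36 rose in TKO cells, 22 of 36 in STOP cells and 16 of 22 in P1 liver, while 21 of 53 fell in pTKO heart, where edgeR called 0 genes without pTKO 1 or 2. Few or none were called elsewhere: 0 of 57 in pTKO brain, kidney and lung, 0 of 25 in pTKO liver, 1 of 54, 1 of 56 and 0 of 56 in P1 heart, kidney and lung, 0 of 49 and 0 of 24 in pIR E18.5 heart and liver, 0 of 36 in STOP against TKO, 0 of 16 in 2C embryos and 0 of 2 in blastocysts. Members without a call still leaned one way in some tissues, with 56 of 56 higher in P1 lung, 49 of 54 in P1 heart, 42 of 56 in P1 kidney and 16 of 16 in 2C embryos (medians 0.347, 0.399, 0.288 and 0.777, against 0.491 in P1 liver). The family was not among the lists fixed in advance and was not tested as a set, with reads shared between their exons not resolved.

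X-linked genes were lower in TKO 1, TKO 2, STOP 1 and STOP 2 than in WT (median log2 shifts -0.79, -0.50, -0.58 and -0.45 over 584 genes), and TKO 3 lay at -0.02. The largest autosome shift was at most 0.324 times the X shift in the shifted libraries, so a lower X dosage in these cultures may explain the shift, and TKO 3 may have kept the WT dosage. Haploid cells and their diploid descendants carry the same number of X per autosome set, so this would need loss of an X in diploid descendants, and neither ploidy nor DNA was measured here. In morula pIR 1 genes of chromosome 5 had a median shift of -0.958, with 80.4% of 739 genes lower and the next chromosome, X, at 0.363. A candidate explanation is 1 missing copy of chromosome 5 in that embryo sample.

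Neighbouring genes moved together in the P1 tissues. On chromosome 4 a run of 25 genes from Atp6v0b to Ppcs was lower in heart, kidney, liver and lung (medians -0.62, -0.45, -0.78 and -0.54). It was picked as the lowest run in heart. The length of a run was set to 25 genes, so its ends need not mark where the change stops. With the gene order permuted, 0 of 200 orders held a run as low in all 4 tissues (farthest -0.22 against -0.45), which argues against a chance order of unrelated genes. Another run, on chromosome 13, reached -0.287, so neighbouring genes moved together elsewhere too. In the chromosome 4 run 80%, 88%, 76% and 96% of the genes were lower in heart, kidney, liver and lung, and 2 were called higher in liver. The pIR libraries lay between -0.35 and -0.84 and the pWT libraries between -0.10 and 0.11, while the E18.5 pIR libraries lay between -0.02 and 0.06. A segment with 1 copy missing in the pIR newborns, whose nearest pIR library outside heart lay at -0.347, or sequence variants of another strain in the segment could give this, and they cannot be told apart without DNA data. On chromosome 11 a run of 25 genes that starts with Col1a1 was higher (medians 0.84, 0.70, 0.29 and 0.45). It was picked as the highest run in heart, and 0 of 200 permuted orders held a run as high in all 4 tissues (farthest 0.232 against 0.291). Another run, on chromosome 18, reached 0.288, so the run does not stand apart from other neighbouring genes that move together.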
